A study of Mus musculus with 30 samples.

How the data were processed

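RNA was measured in 30 libraries of mouse bone marrow-derived macrophages, 3 for each of 10 groups that combine genotype (WT or Ticam2-/-) with no treatment, LPS at 10 ng/mL or LTA at 100 ng/mL for 2 h or 6 h. Groups were taken from the sample labels, and 0 libraries and 0 columns were left out. Per the labels, each replicate held cells of 1 animal, 3 WT and 3 KO animals in all, and red cells were lysed before culture. The labels' harvest text names the 6 h time point alone, while 12 libraries are labelled 2 h, and the labels were followed. Total RNA was extracted per the labels, and the RNA selection and the strand setting of the counting are not given in the sources used here.

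The values analysed were the expected counts per gene that the authors deposited in 1 table of 32361 Ensembl gene IDs. Per the submitters' processing notes, fastp 0.24.0, STAR 2.7.11, SAMtools 1.22.1, featureCounts and Subread 2.1.1 were used with the builds GRCm38 and mm10, and the role and order of these tools and the gene annotation release are not given in the sources used here. Of the deposited values above 0, 25.2% were not whole numbers, so a count can be split over genes, and all values were rounded to whole counts for the tests. Gene symbols and GRCm38 coordinates came from GENCODE M21 by Ensembl ID, which named 26304 of the IDs. The 6057 IDs it did not name held 1.32 to 3.88% of a library's counts and stayed in the tests. Genes with near-identical copies, among them Hba-a1 and Hba-a2, the ferritin gene Fth1 and its pseudogenes, Tgtp1 and Tgtp2, the Bcl2a1, Oas1, Gbp and H2 families, are uncertain in how their counts were split.

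The untreated and 6 h libraries held 10641070 to 13521660 counts and the 2 h libraries 1334784 to 2658329, a median ratio of 6.93. A gene with 0 counts can be present at up to 3 counts by counting error, which is 0.222 to 0.282 CPM in the deeper libraries and 1.13 to 2.25 in the 2 h libraries. The common biological coefficient of variation between replicates was 0.0411.

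Counts were fitted in R 4.3.3 with edgeR 4.0.16. The filterByExpr function (minimum count 10, minimum total 15, by group) left 15119 genes, TMM factors (0.691 to 1.151) scaled the libraries, and a quasi-likelihood model with robust dispersion took 1 coefficient per group over all 30 libraries (20 residual degrees of freedom). The 23 contrasts were each ligand and time against untreated within a genotype, KO against WT in each of 5 conditions, LPS against LTA within a genotype and time, the genotype difference in each response, and the genotype difference between LPS and LTA at each time. P values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05. Fold changes are log2 from the quasi-likelihood fit with edgeR's default prior count, so those of genes with few or 0 counts in a group can be large and uncertain. A prior count of 2 was used only for log2 CPM of single libraries, as in the checks of pairing and of overlap between groups. Standard errors were taken as the absolute fold change over the square root of its quasi-likelihood F. Levels are TMM-normalised CPM, while foreign transcripts are given as CPM of the library total.

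Gene lists were written by name before the data were examined: IRF3 primary targets, interferon-stimulated genes, interferon-inducible GTPases, inflammatory cytokines and chemokines, NF-kB subunits and feedback inhibitors, immediate early genes, secondary inflammatory and antimicrobial genes, MHC class I and class II presentation, co-stimulation, TLR receptors and adaptors, cholesterol biosynthesis, cholesterol efflux and LXR targets, glycolysis, NRF2 genes, cell cycle genes, macrophage identity genes, markers of 7 other cell types, mitochondrially encoded genes and ribosomal protein genes. These 26 lists shared 0 genes and held 519, of which 464 were tested. Markers of T and NK cells and of mast cells and basophils had fewer than 3 tested members and were not tested, which left 24 lists and 552 list tests. Each was tested by camera in limma 3.58.1 with a preset correlation of 0.01, again with a correlation estimated per list, and by fry, adjusted over the lists of a contrast. Single members were counted by their adjusted p over all genes and by a p adjusted over the list alone.

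The groups, contrasts, tests, thresholds, lists and the rule for naming genes were also fixed at that time. The rule named, for KO against WT, WT responses and genotype differences, 24 preset genes, up to 4 members of each list with the smallest p among those past the threshold, and the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of at least 2, a symbol that is not a provisional name, and, except for genotype differences, no overlap between the groups of 3 (chance gives 10.0% for 3 against 3). Part of these genes are left out of the text for space, and a few are not reported here and are not among the named gene results counted under the alternatives.

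Whether replicate numbers pair the libraries was checked by correlating their deviations from the group means over 4605 genes. Within a genotype, where the labels give the same animals to each group, the correlations ran from -0.326 to 0.244 (median 0.005), 7 of 60 being above 0.1, so the pairing rests on the labels. Between WT and KO libraries of a number, which come from different animals, the correlations ran from -0.061 to 0.534 (median 0.056). Fits with the animal as a block were run as an alternative.

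Alternatives tried were relative log expression size factors, no filter on low counts, DESeq2 1.42.0, limma-voom with the animal as a random effect, fits of the groups of a contrast alone, blocks for the animal or the replicate number, and each library left out in turn. Chosen after the data were seen were fits of the untreated and 6 h libraries alone, of the 2 h libraries alone, and of all libraries thinned at random to 1334575 counts, the smallest total of rounded counts, and of libraries scaled by total counts without TMM factors, which takes the sum of counts and not the bulk of the genes as constant. The tests were tested on simulated data of the same size and depth. Of genes changed 2-fold, 68.7% were recovered for KO against WT with LPS at 6 h and 56.7% at 2 h, with 1.45% and 5.83% false among the called, and 0 of 100 unchanged gene sets had a camera p under 0.05. The simulated genes were drawn independently, so the sets do not test camera for lists whose genes vary together. Few genes were changed in the simulation, 67 of 15119 by 2-fold at each time. It called 138 genes with LPS at 6 h and 120 at 2 h, against 9576 and 2472 in the data. The shares recovered and false therefore hold where most genes are unchanged, and do not test the scaling where most genes differ. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.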

Results

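Gene expression was measured by RNA sequencing in macrophages grown from mouse bone marrow in medium containing macrophage colony-stimulating factor. The cells came from wild-type mice (WT) or from mice lacking Ticam2 (Ticam2-/-, written KO). Ticam2 encodes TRAM, the bridging adaptor that links Toll-like receptor 4 to TRIF, the adaptor of the interferon-inducing arm of this receptor. The macrophages were left untreated or received 10 ng/mL lipopolysaccharide (LPS), a Gram-negative cell wall component sensed by Toll-like receptor 4, or 100 ng/mL lipoteichoic acid (LTA), a Gram-positive cell wall component sensed chiefly by Toll-like receptor 2. Exposure lasted 2 h or 6 h. The 10 groups held 3 libraries each, 30 in all, and each library of a genotype came from 1 of 3 animals. The design asks how each genotype responds to each ligand, and how the loss of TRAM changes these responses. The 18 untreated and 6 h libraries held 10641070 to 13521660 counts each. The 12 libraries of the 2 h groups held 1334784 to 2658329. In this report, levels are CPM, scaled by TMM-normalised library sizes, as mean ± SD (n = 3), and log2 fold changes are given ± standard error (n = 3 per group). The calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 over 15119 genes. The TMM factors averaged 0.699 with LPS and 0.748 with LTA at 6 h in WT and 1.00 to 1.15 in the other groups. Scaled by total counts alone, an alternative chosen after the data were seen, the median gene shifted by -0.70 and -0.60 on the log2 scale in the WT responses to LPS and LTA at 6 h, by -0.19 and -0.18 in the KO responses, and by 0.52 and 0.44 in KO against WT.

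Ticam2 (ENSMUSG00000056130, chromosome 18, 46557291 to 46574533 on GRCm38, a protein-coding gene) was lower in every KO group than in its WT counterpart. The untreated WT libraries held 130, 145 and 120 Ticam2 counts, and the untreated KO libraries 10, 9 and 5. With LPS for 6 h the counts were 168, 194 and 196 in WT and 26, 19 and 14 in KO. LTA for 6 h gave 233, 260 and 212 in WT and 10, 15 and 13 in KO. At 2 h the LPS libraries held 22, 18 and 28 counts in WT and 1, 14 and 7 in KO, and the LTA libraries 15, 19 and 20 in WT and 8, 7 and 3 in KO. The KO-to-WT log2 fold change was -4.01 ± 0.21 in untreated cells, -3.80 ± 0.16 with LPS and -4.49 ± 0.17 with LTA at 6 h, and -1.63 ± 0.33 with LPS and -1.81 ± 0.37 with LTA at 2 h. The KO level was 0.625 ± 0.238 CPM in untreated libraries and 3.16 ± 2.21 CPM with LPS for 2 h, a library set with fewer counts. In WT, Ticam2 rose with both ligands at 6 h, by a log2 fold change of 1.11 ± 0.11 with LPS and 1.34 ± 0.10 with LTA. The rise was smaller as CPM of the library total, where WT libraries held 10.49 to 12.57 untreated, 14.54 to 15.69 with LPS and 17.15 to 21.05 with LTA at 6 h. Which part of the gene the KO allele removes is not given in the sources used here, so the remaining counts were not interpreted.

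The 2 h libraries differed from the untreated and 6 h libraries in transcripts of other tissues. Hbb-bs, a haemoglobin gene of red blood cells, averaged 2359 CPM of the library total in the 18 untreated and 6 h libraries and had 0 counts in the 12 libraries of 2 h. Alb, the serum albumin gene of liver, averaged 53.4 CPM at 2 h and had 0 counts in the other 18. A count of 0 allows up to 2.25 CPM in the smallest 2 h library and up to 0.282 in the smallest of the others, for counting error only. Mitochondrially encoded genes took 5.26% to 6.55% of the counts in the means of the 4 groups of 2 h, 3.44% and 3.63% in untreated KO and WT, and 2.85% to 3.04% in the 4 groups of 6 h. No untreated library belongs to the set with Alb counts. Each comparison of a 2 h group with untreated cells therefore also compares the library sets, while comparisons between groups of 1 time point stay within a set.

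**Figure D1:**
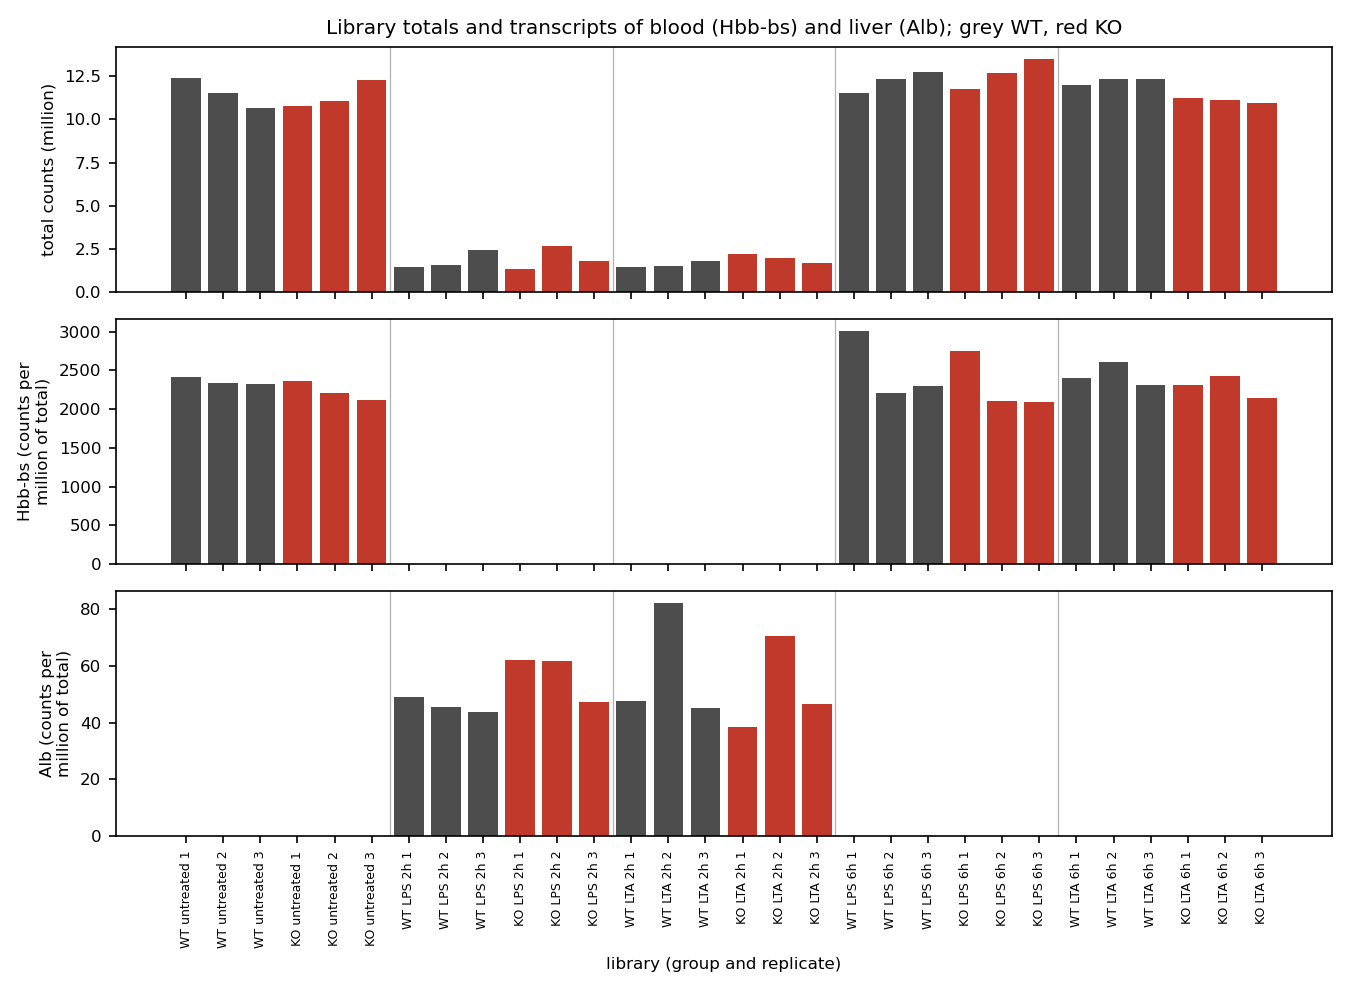
Total counts (upper panel) and CPM of the library total for Hbb-bs (middle) and Alb (lower) in each of the 30 libraries, with WT in grey and KO in red. The 12 libraries of 2 h have the smallest totals, 0 Hbb-bs counts and an average of 53.4 Alb CPM.

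After 6 h of LPS, WT macrophages raised cytokines, interferon-stimulated genes and antimicrobial enzymes together and lowered cell cycle genes. Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), an inflammatory cytokine, went from 7.44 ± 0.859 to 3879 ± 147 CPM, a log2 fold change of 9.02 ± 0.07. Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), a chemokine induced by IRF3 and interferon, went from 92.6 ± 1.25 to 14466 ± 528 CPM (log2 fold change 7.29 ± 0.05). Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, rose by 8.63 ± 0.09 on the log2 scale, and Il12b (ENSMUSG00000004296, chromosome 11, 44400063 to 44414033), a subunit of interleukins 12 and 23, by 9.10 ± 0.14. The early cytokine Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) rose by 5.20 ± 0.05, the NF-kB inhibitor Nfkbia (ENSMUSG00000021025, chromosome 12, 55489410 to 55492647) by 3.60 ± 0.04 and the antiviral gene Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452) by 6.27 ± 0.05. Ifnb1 (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774), the gene of interferon beta, reached 8.13 ± 1.30 CPM from 0.253 ± 0.0757. The largest rises by the naming rule also held Has1, a hyaluronan synthase that went from 0 counts to 12.7 ± 1.29 CPM, Ptx3 (9.15 ± 0.11), a soluble pattern recognition protein, and Il1a (8.95 ± 0.06), a cytokine of the interleukin 1 family. The 5 largest falls were Cdca7 (-6.45 ± 0.22), Ung (-5.92 ± 0.23), Exo1 (-5.51 ± 0.28), Ccne2 (-5.48 ± 0.18) and Nfatc2 (-5.40 ± 0.19). Ccne2 encodes a cyclin of the entry into DNA replication, and Ung and Exo1 encode DNA repair enzymes.

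Of the gene lists fixed beforehand, 31 of 31 inflammatory cytokines and chemokines rose with LPS at 6 h in WT, as did 27 of 27 NF-kB subunits and feedback inhibitors and 29 of 29 secondary inflammatory and antimicrobial genes, the same counts as when adjusted over the list alone. All 12 IRF3 primary targets rose (median log2 fold change 4.86), and so did 49 of 50 interferon-stimulated genes (median 2.40) while 1 fell, again the same counts adjusted over the list alone. Among interferon-inducible GTPases, which act against intracellular microbes, 14 of 15 rose, with Gbp3 at 6.23 ± 0.06 and Gbp2 at 5.79 ± 0.06. All 17 MHC class I presentation genes rose (median 1.59), and all 14 genes of co-stimulation and antigen-presenting cell activation rose, Cd40 by 7.13 ± 0.06. All 34 cell cycle genes fell (median -2.31), among them the replication gene Mcm2 (-3.46 ± 0.08) and the ribonucleotide reductase gene Rrm2 (-4.55 ± 0.07). In cholesterol biosynthesis, 17 of 23 genes fell and 2 rose, with Msmo1 at -2.27 ± 0.06 and Sqle at -1.74 ± 0.07. Camera adjusted p values of these lists ran from 6.4e-34 for interferon-stimulated genes to 1.5e-04 for cholesterol biosynthesis, and from 2.2e-08 for cell cycle genes to 0.0014 for cholesterol biosynthesis with a correlation estimated per list. In all, 10986 genes changed, 5534 up and 5452 down (a majority that turned without the filter, 5760 and 5807, and in a fit of these groups alone, 5004 and 5801), of which 2538 rose and 2667 fell at least 2-fold. With total counts as the scale, 2450 and 9630 genes were called up and down. Markers of erythroid cells and megakaryocytes rose in 8 of 8 cases (camera adjusted p = 0.014, adjusted p = 0.245 with an estimated correlation, 2 rising with total counts). Ribosomal protein genes rose in 26 of 34 cases (median 0.19, camera adjusted p = 0.035, adjusted p = 0.650 with an estimated correlation), while all 34 fell with total counts.

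LTA for 6 h moved the same lists in WT cells. Il6 reached 5215 ± 129 CPM and rose by 9.45 ± 0.07 on the log2 scale, and Csf2, a haematopoietic growth factor gene, rose by 10.47 ± 0.14. Il23a, a subunit of interleukin 23, rose by 9.59 ± 0.17 and Il12b by 9.66 ± 0.14. Cxcl10 rose by 6.18 ± 0.05, Rsad2 by 4.44 ± 0.05 and Ifnb1 by 4.39 ± 0.30. All 31 inflammatory cytokines and chemokines, all 27 NF-kB genes and all 12 IRF3 primary targets rose, also when adjusted over the list alone. Of the interferon-stimulated genes 47 of 50 rose and 3 fell, and 33 of 34 cell cycle genes fell and 1 rose, the same counts adjusted over the list alone. NRF2 and oxidative stress genes rose in 12 of 14 cases, with the thioredoxin reductase gene Txnrd1 at 2.72 ± 0.04 and Gsr, a glutathione reductase, at 2.85 ± 0.05. Among the 5 largest falls were Cnr2 (-6.17 ± 0.33), a cannabinoid receptor, Rasgrp3 (-5.55 ± 0.14), a Ras activator, and E2f2 (-5.40 ± 0.38), a cell cycle transcription factor. In all, 10776 genes changed, 5348 up and 5428 down, a majority that turned in 5 of 9 alternative fits, for example with relative log expression factors (5882 and 4987) and DESeq2 (5642 and 4761). Total counts gave 2375 and 9414. Erythroid and megakaryocyte markers rose in 8 of 8 cases (camera adjusted p = 0.0085, adjusted p = 0.193 with an estimated correlation, 2 rising with total counts). Ribosomal protein genes rose in 28 of 34 (camera adjusted p = 0.011, adjusted p = 0.605 with an estimated correlation), while all 34 fell with total counts.

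Between the ligands at 6 h, WT cells had higher interferon-pathway genes with LPS, while cytokines split. All 12 IRF3 primary targets were higher with LPS (median log2 difference 1.18, camera adjusted p = 2.0e-29), as were all 50 interferon-stimulated genes (median 0.99) and all 15 interferon-inducible GTPases (median 1.27). These counts were unchanged when adjusted over the list alone. Cxcl10 averaged 14466 ± 528 CPM with LPS and 6711 ± 78.1 with LTA, and Rsad2 6625 ± 185 and 1863 ± 67.0. Inflammatory cytokines and chemokines split, with 11 of 31 higher and 18 lower with LPS. That list leaned towards LTA by camera (adjusted p = 0.0023), with an adjusted p of 0.164 with an estimated correlation. Tnf averaged 2106 ± 51.0 CPM with LPS and 4044 ± 64.6 with LTA. NRF2 and oxidative stress genes were lower with LPS in 12 of 14 cases (median -0.56). The comparison called 4810 genes, 2699 higher and 2111 lower with LPS, a majority that turned with total counts (2136 and 3409). The doses of the ligands differ, so the contrast is between these exposures.

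**Figure D2:**
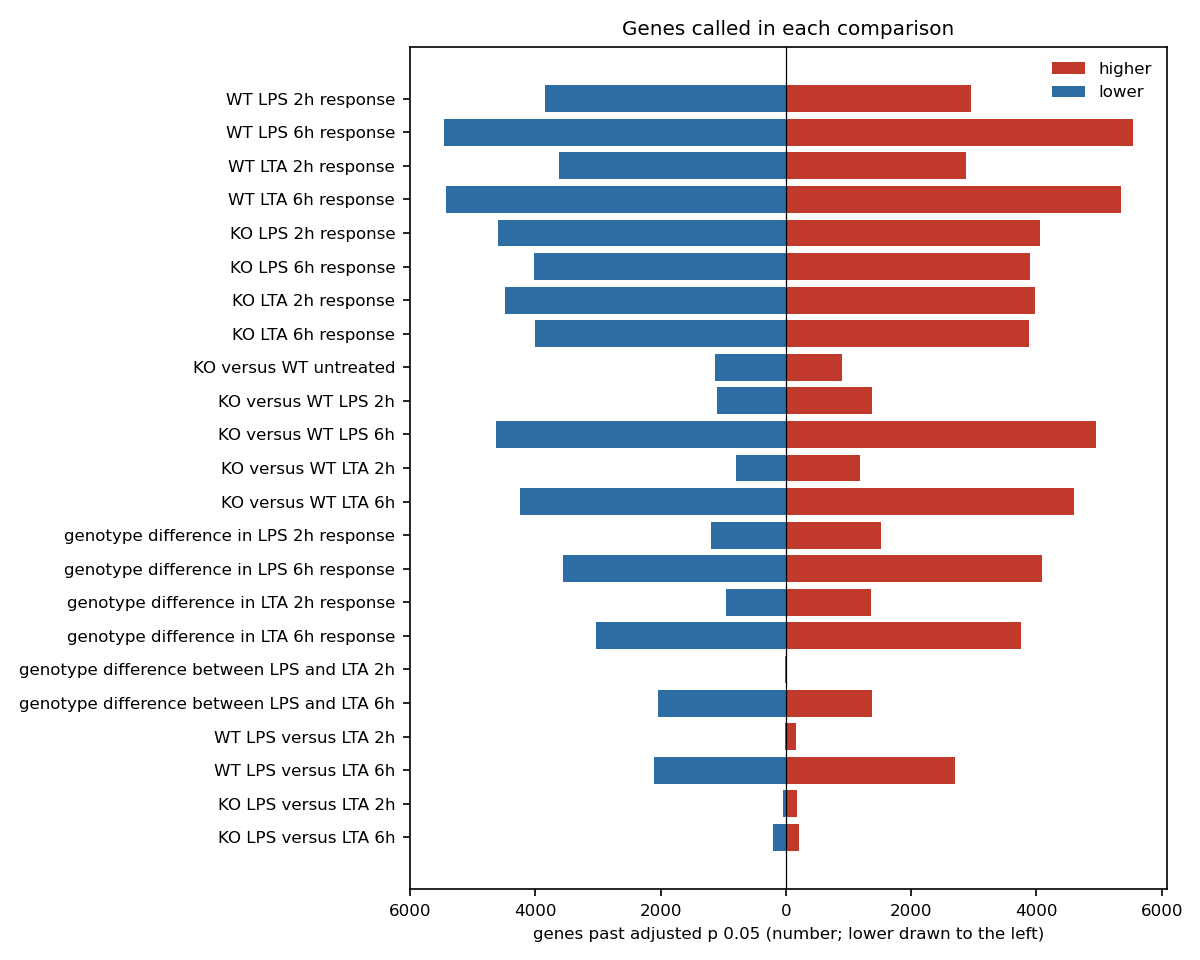
Number of genes past an adjusted p of 0.05 in each of the 23 comparisons, with genes higher drawn to the right (red) and genes lower to the left (blue). Bars of KO against WT reach 4951 and 4625 with LPS at 6 h and 902 and 1130 in untreated cells.

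At 2 h, WT cells given LPS and WT cells given LTA could be compared within 1 library set. LPS gave higher levels of 8 of 12 IRF3 primary targets (10 adjusted over the list alone, median log2 difference 1.02) and of 22 of 31 inflammatory cytokines and chemokines (24 adjusted over the list alone, median 0.71) and 0 were lower. Cxcl10 averaged 1178 ± 51.6 CPM with LPS and 494 ± 7.62 with LTA, and Ifnb1 4.92 ± 1.61 and 0.565 ± 0.0641. Immediate early genes, which respond within minutes of signalling, were higher with LPS in 12 of 26 cases (17 adjusted over the list alone). The comparison called 181 genes, 166 higher and 15 lower with LPS. Against untreated WT cells, all 27 NF-kB genes rose with LPS and all 27 with LTA at 2 h, with Nfkbia at 2.04 ± 0.04 and 1.83 ± 0.04. Cxcl1, a neutrophil chemokine, rose by 6.50 ± 0.07 with LPS and 6.15 ± 0.07 with LTA, Tnf by 5.21 ± 0.05 and 4.82 ± 0.05, and Csf2 by 6.80 ± 0.37 and 5.65 ± 0.50. Inflammatory cytokines and chemokines rose in 27 of 31 cases with LPS and in 26 with LTA (27 and 26 adjusted over the list alone). IRF3 primary targets rose in 8 and fell in 2 of 12 cases with LPS (9 and 3 adjusted over the list alone), and rose in 3 and fell in 6 with LTA (4 and 6 adjusted over the list alone, camera adjusted p = 0.801). Markers of erythroid cells and megakaryocytes moved with the library set, 6 of 8 being lower and 1 higher with LPS at 2 h than in untreated cells, and Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were among the 5 largest falls for both ligands. Markers of fibroblasts and stromal cells were higher in 5 of 9 cases with LPS, Fn1 by 7.64 ± 0.35, and lower in 1, with a camera adjusted p of 0.0067 and an adjusted p of 0.146 with an estimated correlation. The responses called 6798 genes with LPS (2949 up, 3849 down) and 6499 with LTA (2879 up, 3620 down), where DESeq2 turned the majority for both (3243 and 3156, and 3282 and 2891) and relative log expression factors for LTA (3271 and 3221), and these counts hold the difference between library sets as well as that between treatments.

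With LPS for 6 h, KO macrophages fell far short of WT in interferon-pathway genes and in many cytokines, while Tnf stayed close to the WT level. Cxcl10 averaged 167 ± 4.60 CPM in KO and 14466 ± 528 in WT, a log2 fold change of -6.44 ± 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.6e-64, all 3 KO libraries below all 3 WT libraries). Rsad2 was at -6.33 ± 0.05 on the log2 scale, with 82.2 ± 2.98 against 6625 ± 185 CPM. Ifnb1 was at 0.498 ± 0.0766 CPM in KO (log2 fold change -3.99 ± 0.24), the chemokine gene Ccl5 averaged 319 ± 17.4 CPM in KO and 10191 ± 723 in WT, Ifit1 was at -4.61 ± 0.05, the ubiquitin-like modifier Isg15 at -4.75 ± 0.05, the antiviral GTPase Mx1 at -5.47 ± 0.07, and the transcription factor Irf7 at -3.21 ± 0.05. Il6 was at 143 ± 10.2 CPM in KO against 3879 ± 147 in WT (log2 fold change -4.77 ± 0.05), Il12b at -5.45 ± 0.10, Il10, an anti-inflammatory cytokine, at -4.85 ± 0.09, Il1b at -3.10 ± 0.04 and Nos2 at -5.32 ± 0.06. Tnf averaged 1770 ± 91.3 CPM in KO and 2106 ± 51.0 in WT (log2 fold change -0.25 ± 0.04, which turned to 0.27 with total counts). Nfkbia was at -0.73 ± 0.04, the chemokines Cxcl1 and Cxcl2 at -1.63 ± 0.05 and -1.08 ± 0.04, and Acod1 (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573), which makes itaconate, at -2.20 ± 0.04. The largest falls were Lipg (-8.22 ± 0.22), an endothelial lipase gene, the chemokine Cxcl11 (-7.95 ± 0.14), the cytokine Il19 (-7.24 ± 0.19), Trim30c (-7.07 ± 0.44) and Tnc, a matrix glycoprotein. The genes most above WT were Rasgrp3 (5.22 ± 0.14), Cdca7 (4.61 ± 0.30), Ung (4.60 ± 0.28), Nfatc2 (4.42 ± 0.22) and Zfp395 (4.24 ± 0.46).

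By list, all 12 IRF3 primary targets were lower in KO with LPS at 6 h (mean log2 fold change -5.15), as were all 50 interferon-stimulated genes (median -2.80, camera adjusted p = 8.3e-54), all 15 interferon-inducible GTPases (median -4.37) and all 17 MHC class I presentation genes (median -1.51). Inflammatory cytokines and chemokines were lower in 28 and higher in 1 of 31 cases, and 2 were not called. NF-kB subunits and feedback inhibitors were lower in 24 of 27 cases with a smaller median of -1.23, for example Nfkb2 at -2.07 ± 0.04 and Socs3 at -1.91 ± 0.04. Secondary inflammatory and antimicrobial genes were lower in 27 of 29 cases (median -2.20), and co-stimulation genes in 12 of 14, with the interleukin 15 gene Il15 at -4.65 ± 0.06. Cell cycle genes were higher in KO in 32 of 34 cases (median 1.79), among them Rrm2 (3.41 ± 0.08) and Ccna2 (3.18 ± 0.10), and cholesterol biosynthesis genes in 21 of 23 (median 0.93), among them Msmo1 (2.03 ± 0.07) and Sqle (1.78 ± 0.07). The counts of these lists were the same adjusted over the list alone. MHC class II presentation genes were lower in 8 of 9 cases (camera adjusted p = 4.9e-04, and adjusted p = 0.051 with an estimated correlation). The comparison called 9576 genes, 4951 higher and 4625 lower in KO, of which 1802 and 1876 differed at least 2-fold. The majority turned with relative log expression factors (4335 and 5238), with DESeq2 (4082 and 4955) and with every library thinned to the smallest total (2377 and 2621, 4998 in all), and total counts gave 9268 and 2191, so neither direction prevailed.

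With LTA for 6 h, KO cells also lacked most of the interferon-pathway rise and had lower cytokine expression than WT. Cxcl10 averaged 156 ± 3.65 CPM in KO and 6711 ± 78.1 in WT (log2 fold change -5.43 ± 0.04, n = 3 per group). Rsad2 was at -4.58 ± 0.05, Ifnb1 at -3.72 ± 0.28, Ccl5 at -4.82 ± 0.05, Isg15 at -3.96 ± 0.05 and Mx1 at -3.86 ± 0.08. Il6 averaged 159.9 ± 4.34 CPM in KO and 5215 ± 129 in WT (log2 fold change -5.03 ± 0.05), and Tnf 1766 ± 31.7 and 4044 ± 64.6 (log2 fold change -1.20 ± 0.04). Il23a (-8.19 ± 0.16), Il12b (-6.44 ± 0.10), the matrix gene Tnc, the growth factor Areg (-5.93 ± 0.15) and Hdc (-5.91 ± 0.16), the histamine-forming enzyme, were furthest below WT. Rasgrp3 (5.72 ± 0.14), the sialyltransferase St6gal1 (4.72 ± 0.16), Cd28 (4.66 ± 0.09), Cnr2 (4.60 ± 0.45) and Zfp395 (4.48 ± 0.56) were furthest above. All 12 IRF3 primary targets (median -3.92), 49 of 50 interferon-stimulated genes (median -1.95, camera adjusted p = 1.1e-47), 30 of 31 inflammatory cytokines and chemokines (median -3.39) and 25 of 27 NF-kB genes (median -1.20) were lower in KO, the same counts as adjusted over the list alone. Cell cycle genes were higher in 31 of 34 cases (32 adjusted over the list alone) and cholesterol biosynthesis genes in 20 of 23. Glycolysis and glucose uptake genes were lower in 14 of 18 cases, with the hexokinase Hk2 at -1.85 ± 0.05 and the glucose transporter Slc2a1 at -1.41 ± 0.04, a majority that turned with total counts (6 lower, 8 higher). Mitochondrially encoded genes were lower in 9 of 13 cases (10 adjusted over the list alone, camera adjusted p = 0.078), while 8 were higher and 0 lower with total counts. The comparison called 8841 genes, 4604 higher and 4237 lower in KO, and the majority turned with relative log expression factors (3980 and 4994), with DESeq2 (3721 and 4622) and with libraries thinned to the smallest total (2092 and 2214, 4306 in all). Total counts gave 8906 and 1836. Across all 15119 genes the KO-to-WT log2 fold changes with LPS and with LTA at 6 h, which share animals and no libraries, had a Pearson r of 0.85 and a Spearman rho of 0.825, genes not being independent replicates. Of 7470 genes called in both, 7232 went the same way, against 1508 higher and 1296 lower in both for independent lists.

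**Figure D3:**
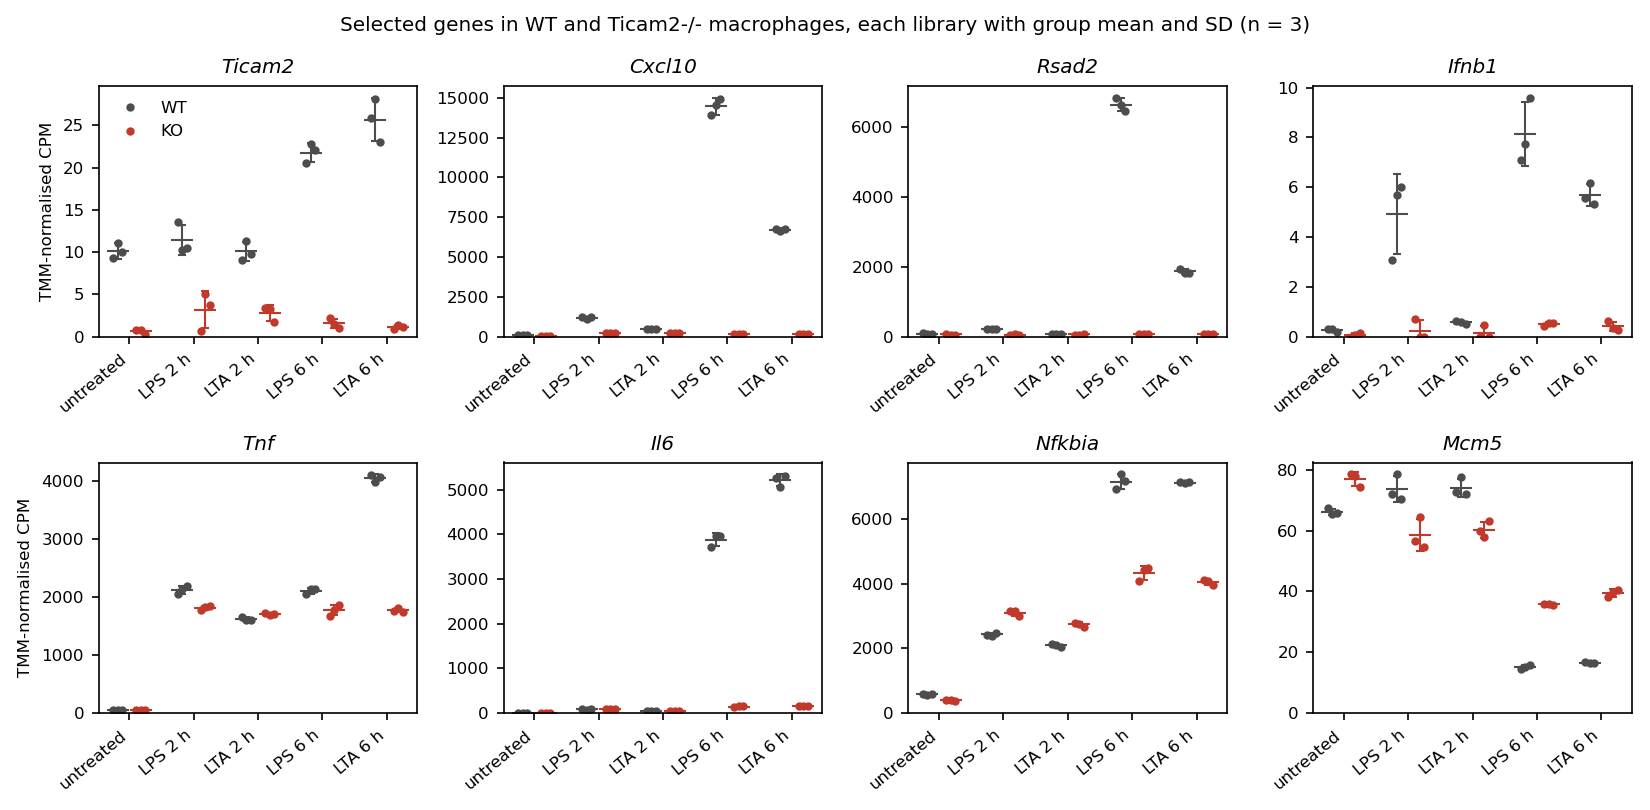
TMM-normalised CPM of 8 genes in WT (grey) and KO (red) libraries, with each point a library and each bar the group mean with its SD (n = 3), on linear axes from 0. For Cxcl10 the WT LPS 6 h group stands at 14466 and the KO LPS 6 h group at 167.

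KO cells still responded to both ligands at 6 h. All 27 NF-kB genes rose in KO with LPS (median 2.57) and all 27 with LTA (median 2.50), against WT medians of 3.61 and 3.59. Inflammatory cytokines and chemokines rose in 31 of 31 cases with LPS (median 3.56, against 6.08 in WT) and in 30 with LTA. Interferon-stimulated genes did not pass as a group in KO with LPS, 13 of 50 rising and 15 falling (13 and 16 adjusted over the list alone, camera adjusted p = 0.210). With LTA 9 rose and 22 fell, and the list leaned down by camera (adjusted p = 0.039, and adjusted p = 0.117 with an estimated correlation; adjusted p = 0.053 without replicate 1 of KO LTA at 6 h). Of the IRF3 primary targets 7 of 12 rose and 3 fell with LPS in KO (median 0.54). Cell cycle genes fell in all 34 cases with LPS (median -0.96) and in all 34 with LTA (median -0.87). The KO responses called 7908 genes with LPS and 7898 with LTA, of which 1008 and 996 rose at least 2-fold. Between LPS and LTA at 6 h the KO libraries differed in 402 genes, 203 higher and 199 lower with LPS (200 and 210 in a fit without the 2 h libraries and 180 and 246 with total counts), including 4 of 12 IRF3 primary targets (6 adjusted over the list alone, median 0.17) and 14 of 26 immediate early genes higher with LPS. Thinned to the smallest total, the libraries gave 35 genes (17 and 18), and these groups alone 216. The count from all libraries also depended on single ones: without replicate 1, 2 or 3 of KO LPS at 6 h it was 852, 178 or 190, and without replicate 1, 2 or 3 of KO LTA at 6 h 259, 216 or 254.

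Most genes that WT cells induced at least 2-fold by 6 h rose less in KO, and most that WT cells lowered at least 2-fold fell less. The KO response to LPS at 6 h minus the WT response was -5.77 ± 0.07 on the log2 scale for Rsad2, -5.74 ± 0.06 for Cxcl10, -5.48 ± 0.51 for Il12b, -4.85 ± 0.14 for Mx1, -4.60 ± 0.32 for Nos2 and -4.56 ± 0.13 for Il6. For Tnf the difference was 0.07 ± 0.06 (adjusted p = 0.329 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), which did not pass the threshold. With total counts it was 0.58 and passed (adjusted p = 1.4e-13 by the same test). Nfkbia differed by -0.12 ± 0.05 (adjusted p = 0.048, and adjusted p = 0.0561 with the animal as a block, both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Cxcl2 by -0.23 ± 0.06, and both turned with total counts (0.38 and 0.28). With LTA the differences were -6.47 ± 0.53 for Il12b, -4.82 ± 0.13 for Il6, -4.73 ± 0.06 for Cxcl10, -4.02 ± 0.07 for Rsad2, -2.77 ± 0.14 for Cxcl1 and -0.87 ± 0.06 for Tnf. All 50 interferon-stimulated genes responded less in KO to LPS (median difference -2.53) and 47 of 50 to LTA (median -1.74, 48 adjusted over the list alone). The cell cycle list differed in the other direction, 29 of 34 genes falling less in KO with LPS, for example Rrm2 (3.12 ± 0.09) and Mcm2 (2.42 ± 0.10). Of 2538 genes that rose at least 2-fold with LPS at 6 h in WT, 1816 (71.6%) had a smaller response in KO by the interaction test, 36 a larger one, and 865 also rose at least 2-fold in KO. Of 2667 that fell at least 2-fold, 2104 (78.9%) fell less in KO, against 720 for independent lists. With LTA the numbers for rises were 2160, 1431 (66.2%), 21 and 883, and 2028 (76.3%) of 2658 fell less, 660 for independent lists. Independent lists would give 597 and 434 genes with a smaller response and simulated genotypes with equal responses gave 0, and since the WT libraries enter both tests, part of the excess may come from them. With total counts as the scale, 915 of 1410 genes raised by LPS and 736 of 1248 raised by LTA responded less in KO. On that scale 4731 of 5448 and 4159 of 4997 lowered genes fell less. At 2 h, where the response also spans the library sets, 37 of 1019 genes raised by LPS in WT had a smaller and 174 a larger response in KO. With LTA at 2 h these were 24 and 142 of 1011. Of genes lowered at 2 h, 46 of 1193 fell less and 56 more in KO with LPS, and 51 of 1150 less and 38 more with LTA. At 6 h the interaction called 7641 genes for LPS (4082 up, 3559 down) and 6787 for LTA (3752 up, 3035 down), and both majorities turned with relative log expression factors (3560 and 4141 for LPS, 3209 and 3697 for LTA) and DESeq2 (3223 and 3878 for LPS, 2871 and 3450 for LTA). Total counts gave 8452 and 1647 for LPS and 7971 and 1262 for LTA.

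The KO-to-WT difference at 6 h itself differed between the ligands, whose doses were unequal. KO libraries differed between LPS and LTA in 402 genes and WT libraries in 4810. At least 2-fold, 6 were higher and 2 lower with LPS in KO, against 653 and 174 in WT. The median LPS-to-LTA difference of interferon-stimulated genes was 0.05 in KO and 0.99 in WT. For that list the test thus largely restates the WT difference between the ligands. The KO-to-WT difference was larger with LPS for Rsad2 (difference of the KO-to-WT log2 fold changes -1.75 ± 0.06), Nos2 (-1.76 ± 0.09), Mx1 (-1.61 ± 0.12) and Irf7 (-1.25 ± 0.07), and larger with LTA for Csf2 (4.75 ± 0.15), Il23a (4.44 ± 0.59), Areg (4.06 ± 0.36), Cxcl1 (1.91 ± 0.07) and Tnf (0.95 ± 0.05). All 50 interferon-stimulated genes lay on the LPS side (median -0.89, camera adjusted p = 3.4e-57), as did 11 of 12 IRF3 primary targets, the same counts as adjusted over the list alone. Inflammatory cytokines and chemokines had 16 of 31 genes on the LTA side and 9 on the LPS side (17 and 9 adjusted over the list alone), with a camera adjusted p of 2.3e-05 and an adjusted p of 0.055 with an estimated correlation. This test called 3425 genes, 1382 up and 2043 down, a majority that turned with total counts (2304 and 1664).

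At 2 h, within the set of 2 h libraries, KO cells given LPS were below WT in interferon-pathway and immediate early genes and above WT in NF-kB genes. The genotype contrast in this set is in some doubt, as Ticam2 was less reduced in KO than in the other libraries. In addition, 72 genes chosen for a steady KO difference in untreated and 6 h libraries (median 1.13) had a median of -0.04 with LPS at 2 h. Mixing of WT and KO reads at 2 h was neither borne out nor excluded, so the sizes given here are uncertain. Cxcl10 averaged 223 ± 3.93 CPM in KO and 1178 ± 51.6 in WT (log2 fold change -2.40 ± 0.05), Rsad2 was at -1.89 ± 0.08, Oasl1 at -2.61 ± 0.14 and Ifnb1 at -4.82 ± 0.77, with 0.236 ± 0.409 against 4.92 ± 1.61 CPM. The KO libraries held 1, 0 and 0 Ifnb1 counts, so the size of this fall is not well determined. The immediate early transcription factors Egr1 and Fos were at -3.03 ± 0.24 and -2.23 ± 0.17, and Dusp1, a phosphatase that limits MAP kinases, at -2.50 ± 0.09. Nos2 was above WT by 2.95 ± 0.24, the acute phase gene Saa3 by 2.33 ± 0.06, the scavenger receptor Marco by 2.37 ± 0.16 and Nfkbia by 0.35 ± 0.04, while Tnfaip3, another NF-kB inhibitor, was at -1.07 ± 0.06. Tnf was at -0.23 ± 0.04, and Il6 at 0.12 ± 0.09 did not pass the threshold. The largest differences were Areg (-5.20 ± 0.54), Il23a (-4.96 ± 0.80), BC147527 (-4.19 ± 0.90), Lpar6 (-3.67 ± 0.54) and Cnr2 (-3.50 ± 0.60) below WT, and Zfp811 (3.99 ± 0.44), Ppfia3 (3.79 ± 0.32), Lad1 (3.19 ± 0.30), Nos2 and the kinase Pim2 (2.71 ± 0.25) above it. IRF3 primary targets were lower in 10 of 12 cases (median -1.32, camera adjusted p = 1.1e-30) and immediate early genes in 18 of 26 (median -0.71), the same counts adjusted over the list alone. NF-kB genes were higher in 23 of 27 cases (24 adjusted over the list alone, median 0.78) and secondary inflammatory and antimicrobial genes in 16 of 29 (17 adjusted over the list alone). Inflammatory cytokines and chemokines had 9 of 31 higher and 11 lower, and the list did not pass as a group (camera adjusted p = 0.363). The comparison called 2472 genes, 1377 higher and 1095 lower in KO. The majority turned in 4 of 9 alternative fits, among them those of the 2 h libraries alone (1182 and 1207), of these groups alone (1187 and 1264) and with total counts (913 and 1485). Ribosomal protein genes were higher in 7 and lower in 0 of 34 cases (8 higher adjusted over the list alone, median 0.10, camera adjusted p = 6.1e-04, adjusted p = 0.465 with an estimated correlation), with 1 higher and 1 lower with total counts. At this depth, simulated 2-fold changes were recovered in 56.7% of cases, against 68.7% with LPS at 6 h.

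LTA for 2 h gave a similar picture with smaller interferon-pathway differences, and the same doubt about the genotype contrast in the 2 h set applies to their sizes. The compared groups differed in the share of mitochondrially encoded genes (6.55% ± 0.336 in WT and 5.26% ± 0.300 in KO, SD, n = 3) and of the 10 most abundant genes (15.6% ± 0.675 and 14.0% ± 0.307). With LPS at 2 h the mitochondrial shares were 5.69% ± 0.285 and 5.39% ± 0.472. With LTA at 2 h Cxcl10 was at -1.15 ± 0.05 in KO against WT, Rsad2 at -0.32 ± 0.09, Isg15 at -0.50 ± 0.07 and Il12b at -1.15 ± 0.28, while Ifit1 at -0.17 ± 0.09 and Tnf at 0.08 ± 0.04 did not pass the threshold. Nos2 (2.06 ± 0.21), Marco (2.42 ± 0.19), Acod1 (0.75 ± 0.05), Cd40 (0.99 ± 0.09) and Nfkbia (0.39 ± 0.04) were higher in KO, and Egr1 (-1.51 ± 0.32), Areg (-3.69 ± 0.74) and Gpr183 (-3.18 ± 0.43), an oxysterol receptor, were lower. IRF3 primary targets were lower in 6 of 12 cases (median -0.65), NF-kB genes higher in 22 of 27 (24 adjusted over the list alone) and NRF2 genes higher in 12 of 14 (13 adjusted over the list alone), with the autophagy adaptor Sqstm1 at 1.33 ± 0.05. Ribosomal protein genes were higher in 10 and lower in 0 of 34 cases (12 higher adjusted over the list alone, camera adjusted p = 9.7e-05, adjusted p = 0.411 with an estimated correlation), with 1 higher with total counts. The comparison called 1972 genes, 1184 higher and 788 lower in KO, 60.0% of them higher. A fit of the 2 h libraries alone called 1862, 49.2% of them higher. With total counts 836 and 1047 were higher and lower. The KO effect with LPS exceeded that with LTA at 2 h for Rsad2 (-1.57 ± 0.12), Oasl1 (-1.45 ± 0.24), Cxcl10 (-1.25 ± 0.07), Fos (-1.21 ± 0.24), Ifit1 (-1.13 ± 0.11), Dusp1 (-0.98 ± 0.16), Isg15 (-0.85 ± 0.09) and Tnf (-0.31 ± 0.06), while Saa3 (0.70 ± 0.09) differed in the other direction, and this test called 19 genes, 1 up and 18 down.

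Against untreated cells, KO responses at 2 h covered 8641 genes with LPS and 8463 with LTA, all 27 NF-kB genes rising with each ligand (medians 2.89 and 2.61). Between LPS and LTA at 2 h the KO libraries differed in 211 genes, 172 higher and 39 lower with LPS, with 14 of 31 inflammatory cytokines and chemokines (16 adjusted over the list alone) among the higher ones. The genotype difference in the 2 h response was 3.67 ± 0.36 for Nos2, 2.08 ± 0.07 for Acod1, -1.71 ± 0.06 for Cxcl10, -1.33 ± 0.09 for Rsad2 and -3.02 ± 0.30 for Egr1 with LPS, and 2.78 ± 0.33 for Nos2, 2.20 ± 0.07 for Acod1 and -1.49 ± 0.36 for Egr1 with LTA. NF-kB genes rose more in KO in 24 of 27 cases with LPS (25 adjusted over the list alone) and in 25 with LTA. Cell cycle genes fell more in KO in 26 of 34 cases with LPS (29 adjusted over the list alone). These tests called 2708 genes for LPS (1513 up, 1195 down) and 2321 for LTA (1364 up, 957 down), majorities that turned with total counts (1065 and 1726 for LPS, 1003 and 1324 for LTA). Both set 2 h libraries against untreated libraries of the other set. A set of 112 genes was chosen for the same direction of KO-to-WT difference in untreated cells and with LPS at 6 h, without use of the LTA libraries. In that direction, these genes had a median log2 difference of 1.13 with LTA at 6 h and of -0.06 with LTA at 2 h, where 13 were called in that direction and 16 in the other.

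**Figure D4:**
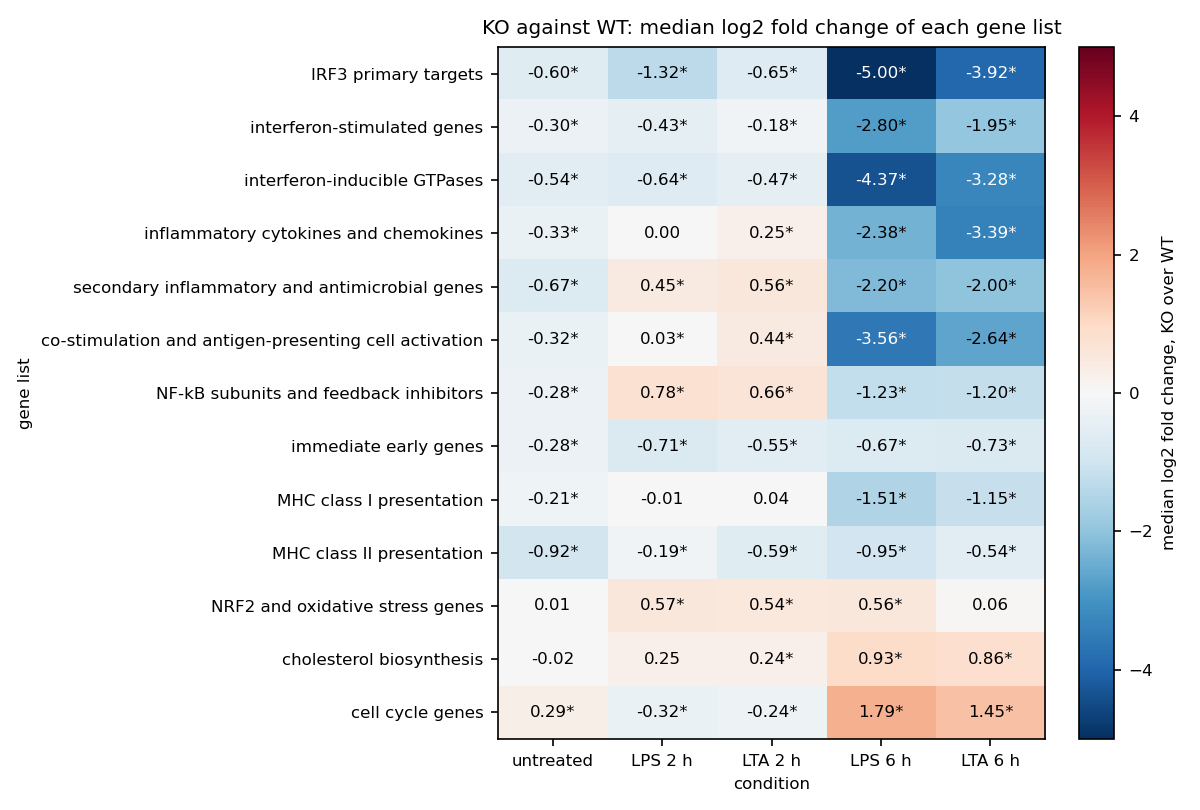
Median log2 fold change of KO over WT for 13 gene lists (vertical axis) in 5 conditions (horizontal axis), coloured from blue (lower in KO) to red (higher), with an asterisk where the camera adjusted p was below 0.05. Interferon-stimulated genes go from -0.30 in untreated cells to -2.80 with LPS at 6 h, while NF-kB genes go from 0.78 with LPS at 2 h to -1.23 at 6 h.

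Untreated KO macrophages differed from untreated WT in fewer genes than KO and WT cells did after 6 h of either ligand. Interferon-stimulated genes were lower in 40 of 50 cases (43 adjusted over the list alone, median -0.30, camera adjusted p = 1.2e-35), among them Isg15 (-0.81 ± 0.05), Ifit1 (-0.69 ± 0.05) and Mx1 (-0.62 ± 0.10). Cxcl10 averaged 57.1 ± 0.862 CPM in KO and 92.6 ± 1.25 in WT (log2 fold change -0.70 ± 0.04). Secondary inflammatory and antimicrobial genes were lower in 22 of 29 cases (median -0.67), with Acod1 at -1.45 ± 0.05 and the prostaglandin synthase Ptgs2 at -0.85 ± 0.08. MHC class II presentation genes were lower in 8 of 9 cases (median -0.92), including H2-Ab1 (-1.24 ± 0.05) and the invariant chain Cd74 (-0.92 ± 0.04), the same counts adjusted over the list alone. Of other cell type markers, those of dendritic cells were lower in 2 of 3 cases (camera adjusted p = 0.04, adjusted p = 0.1 with an estimated correlation), those of B cells higher in 1 of 3 (camera adjusted p = 0.01, estimated 0.056) and those of erythroid cells and megakaryocytes lower in 1 of 8 (camera adjusted p = 0.034, estimated 0.299). NF-kB genes were lower in 15 of 27 cases (16 adjusted over the list alone), with Nfkbia at -0.60 ± 0.04. Cell cycle genes were higher in 21 of 34 cases (25 adjusted over the list alone, median 0.29), for example Top2a (0.41 ± 0.05) and Birc5 (0.39 ± 0.05). Apart from Ticam2, the genes furthest below WT were the formyl peptide receptor Fpr1 (-1.98 ± 0.14), the membrane metalloproteinase Mmp14 (-1.95 ± 0.11), H2-M2 (-1.93 ± 0.20) and Cd38 (-1.87 ± 0.43). Those furthest above were Wdfy1 (2.07 ± 0.08), Rab4a (1.91 ± 0.15), the mitochondrial transhydrogenase Nnt (1.06 ± 0.10), Tox2 (0.99 ± 0.15) and the cyclin-dependent kinase inhibitor Cdkn1c (0.93 ± 0.11). Ifnb1 (-1.55 ± 0.74), Il6 (-0.21 ± 0.11) and Egr1 (-0.01 ± 0.15) did not pass the threshold. The comparison called 2032 genes, 902 higher and 1130 lower in KO, 28 and 96 of them at least 2-fold, a majority that turned with total counts (1053 and 953). With every library thinned to the smallest total, 438 genes were called, 28.5% of them higher in KO against 44.4% at full depth.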

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

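All tests weighed in this part, the splits of the libraries included, were chosen only after the results were seen, apart from the interaction tests themselves.

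The WT and KO macrophages differed in their responses by a test of the difference itself. The response to LPS differed between genotypes in 2708 genes at 2 h and 7641 at 6 h, and the response to LTA in 2321 genes at 2 h and 6787 at 6 h. The KO-to-WT log2 fold change differed between the ligands in 19 genes at 2 h and 3425 at 6 h. The 6 animals can be divided into groups of 3 in 10 ways, the real one included, too few for a share under 0.05. The real split was the 1 with as many genes in each of these 6 comparisons, and the highest count of another split was 0 in each. Every other split mixes WT and KO libraries within groups and so raises the estimated spread, so low counts there could be foreseen.

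The KO effect on interferon-pathway genes at 6 h appeared with LTA as well as with LPS, although TRAM is the adaptor of Toll-like receptor 4. Interferon-stimulated genes were lower in KO in 49 of 50 cases with LTA, with Cxcl10 at -5.43 and Mx1 at -3.86 on the log2 scale. A complete failure of KO cells to respond to LTA was argued against, since 27 of 27 NF-kB genes rose in KO with LTA. A response that is weaker in general was not excluded by this count. With LTA at 6 h, 996 genes rose at least 2-fold in KO and 2160 in WT. Unequal depth was argued against, since 49 interferon-stimulated genes were still lower in KO after every library was thinned to 1 total. Trace LPS activity in the LTA treatment and an action of TRAM downstream of the LTA receptor remain open, as both may give KO effects that run together across genes, and the Pearson r between the ligands was 0.85. These are not the only candidates, since a difference in genetic background between the WT and KO animals was not tested. Already in untreated cells, 2032 genes were called between KO and WT and could not be assigned to the loss of TRAM.

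The 2 h libraries differed from the untreated and 6 h libraries in transcripts of blood, brain and liver. Summed blood markers, of which Pf4 was found in both sets, averaged 6576 CPM in untreated and 6 h libraries and 340.4 at 2 h, and varied 1.36-fold within the higher set, which is in line with blood RNA or reads at 1 level in that set as a candidate source, red cell lysis before culture notwithstanding. Brain markers (118 against 26.2, Mbp the most abundant at 51.2 against 23.7) varied 1.43-fold and liver markers (0.830 against 69.8) 2.01-fold within a set, and both stayed open because the difference between sets or the spread within one missed the bound that had been set. The 112 genes chosen for a KO difference in untreated and LPS 6 h libraries were used to weigh low depth and mixing. With LTA at 6 h in thinned libraries their median was 1.21. Thinning at random leaves the expected ratio unchanged, so this could be foreseen. It shows only that fewer counts alone keep such a median. Mixing of WT and KO reads at 2 h was neither borne out nor excluded. With LTA at 2 h the median of these genes was -0.06 (quartiles -0.65 and 0.56), not above 0 as set for mixing. Called the same way were 13 and the opposite way 16, which mixing alone would not give but mixing with an effect of time may. Of 72 genes steady with LTA at 6 h too, 9 were called the same way and 12 the opposite way with LPS at 2 h. With LTA at 2 h these were 11 and 8. Ticam2 was not part of these tests. At 2 h it stood at 0.708, 5.005 and 3.776 CPM in the KO libraries with LPS and 3.402, 3.239 and 1.673 with LTA. Untreated KO libraries stood at 0.807, 0.713 and 0.355 CPM. WT libraries ranged from 9.1 to 13.5 CPM at 2 h and from 9.28 to 11.1 untreated. This narrower gap at 2 h runs the way that mixing would give, on 1 to 14 counts per KO library at 2 h, and leaves the question open. The library set is confounded with the 2 h time point, so a difference between library batches and an effect of time cannot be told apart in the 2 h responses and their genotype differences.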

How the results depend on the processing

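The alternatives are named in the processing summary, and the thinned fits, the fits of part of the libraries and total counts as the scale were chosen after seeing the data. Relative log expression factors, no filter, DESeq2 and total counts each left all 23 counts of called genes within 1.5 times the value reported, voom 21 and fits of the contrast's groups 22. Voom called 10 genes for the KO effect by ligand at 2 h and 138 for LPS against LTA in KO at 2 h, and the groups alone gave 216 for LPS against LTA in KO at 6 h, where the cause was not tested. Leaving out 1 library moved that last count to 178 to 852 and kept the other 22 within 1.5 times. Thinning every library to 1334575 counts, which leaves fewer counts, gave 6599, 6400, 3421 and 3401 genes for the 6 h responses (WT LPS, WT LTA, KO LPS, KO LTA), 438, 4998 and 4306 for KO against WT untreated and with LPS and LTA at 6 h, 1441, 3395, 1269 and 2520 for the genotype difference (LPS 2 h, LPS 6 h, LTA 2 h, LTA 6 h), 1080 for the KO effect by ligand at 6 h, and 1843 and 35 for LPS against LTA at 6 h in WT and KO. Reversed in the thinned fit were Cd40 in KO against WT untreated (0.006), Gata2 in the WT response to LPS (-1.75) and LTA (-1.75) at 6 h, mt-Atp8 in the WT LTA 6 h response (-0.48), Egr1 (0.062) and S100a8 (0.007) in the genotype difference with LPS and LTA at 6 h, and Il10 in the KO effect by ligand at 6 h (0.73). Reversed with total counts, which leave out the TMM factors that differ between these groups, were in KO against WT with LPS at 6 h Tnf (0.27), Itgax (0.12), mt-Co1 (0.047), mt-Co2 (0.37), Rps24 (0.22), Rps9 (0.27) and Rps20 (0.31), with LTA at 6 h mt-Co1 (0.065), mt-Co3 (0.20), mt-Nd4 (0.20), Rps9 (0.20), Rps24 (0.20), Rpl19 (0.20) and Rpl27 (0.20), in the WT LPS 6 h response Cd74 (-0.14), H2-Aa (-0.39), H2-Eb1 (-0.36), Mmp8 (-0.27), S100a9 (-0.16), Itgax (-0.19), Alas2 (-0.077), mt-Co1 (-0.35), mt-Nd5 (-0.096), Rpl19 (-0.24), Rps9 (-0.28) and Rps24 (-0.33), in the WT LTA 6 h response Cd74 (-0.14), H2-Eb1 (-0.33), Mmp8 (-0.24), Itgax (-0.21), Alas2 (-0.057), Sparc (-0.033), mt-Nd5 (-0.088), mt-Co3 (-0.47), mt-Atp8 (-0.32), Rpl19 (-0.11), Rpl4 (-0.25), Rps9 (-0.28) and Rpl5 (-0.28), and in the genotype difference with LPS at 6 h Cxcl2 (0.28), Nfkbia (0.38), Cd74 (0.24), H2-Ab1 (0.33), mt-Co1 (0.13), mt-Co2 (0.32), mt-Atp6 (0.38), mt-Co3 (0.35), Rps20 (0.21), Rps24 (0.19) and Rps9 (0.25) and with LTA at 6 h Nfkbia (0.20), Cd74 (0.16), mt-Co3 (0.12), mt-Atp6 (0.22), mt-Co2 (0.23), mt-Co1 (0.15), Rps9 (0.18), Rps24 (0.17) and Rpl19 (0.17). The direction that held more of the called genes turned under an alternative in 20 of 23 contrasts. The percent of called genes that were higher moved by over 10 points with total counts in 15 contrasts, in the thinned fit for KO against WT untreated (28.5 against 44.4), the KO effect by ligand at 6 h (27.4 against 40.4) and LPS against LTA in WT at 6 h (68.5 against 56.1), and for KO against WT with LTA at 2 h with the replicate number as a replicate block (49.7 against 60.0) and in the fit of 2 h libraries (49.2).

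With the animal as a replicate block, the counts of the 18 contrasts that allow it stayed within 1.5 times, for example 10974 for WT LPS at 6 h and 7667 for the genotype difference with LPS at 6 h. Camera with this block changed 3 list calls to not passing and 5 to passing, none of them described above, and apart from Nfkbia it changed no call of a gene described. With the replicate number as a block, which WT and KO libraries from different animals share, 9695 genes were called for KO against WT with LPS at 6 h. Correlations between WT and KO libraries of a number ran from -0.061 to 0.534, and 4 of 15 were above 0.1. With LPS at 6 h they were 0.534 for replicate 1 and 0.421 for replicate 3. A library was closest to its own number in 18 of 30 cases between genotypes and in 39 of 120 within a genotype. Libraries of a number may therefore share something other than the animal, and its source was not tested. Estimated correlations ended 79 of 552 list calls and fry ended 8 and added 120. Of 1521 named gene results, 1503 kept their call with relative log expression factors, 1390 with total counts, 1490 with DESeq2 (where 6 without an adjusted p counted as not called) and 1314 after thinning. With each library left out in turn, 12137 of 12444 such results kept their call, 266 lost it and 0 called genes changed sign, and 12 of 870 results of the interferon and inflammatory lists lost their call. Simulated 2-fold changes were recovered in 53.7% of cases for the genotype difference with LPS at 2 h and 58.2% at 6 h, the former resting on the smaller libraries.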

Other observations

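Of the tests in this part, the one on genes flanking Ticam2 was planned, and the sex, resting overlap, time course and pseudogene tests and the splits were chosen only after the results were seen.

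TLR receptors and adaptors rose in 17 and fell in 7 of 25 cases with LPS at 6 h in WT and were lower in KO in 17 and higher in 8 (camera adjusted p = 0.0077, adjusted p = 0.048 with an estimated correlation). Glycolysis genes rose in 16 of 18 cases with LPS at 6 h in WT (8 rising and 9 falling with total counts as the scale) and in 16 in KO. Macrophage identity genes split in KO against WT with LPS at 6 h, 12 of 29 higher and 14 lower (camera adjusted p = 0.857), and cholesterol efflux and LXR targets had 5 of 12 higher and 5 lower (camera adjusted p = 0.857). Ribosomal protein genes had 4 of 34 higher and 9 lower (camera adjusted p = 0.854), and mitochondrially encoded genes 2 of 13 higher and 6 lower (camera adjusted p = 0.600). With total counts as the scale these directions turned, 21 macrophage identity genes being higher and 6 lower, all 34 ribosomal protein genes higher, and 9 mitochondrially encoded genes higher and 0 lower. With LTA at 6 h ribosomal protein genes had 0 higher and 17 lower (camera adjusted p = 0.06), and all 34 higher with total counts. Markers of other cell types, given as lower and higher in KO, numbered 4 and 0 of 6 for neutrophils, 2 and 1 of 3 for dendritic cells, 1 and 1 of 3 for B cells, 7 and 1 of 8 for erythroid cells and megakaryocytes and 3 and 0 of 9 for fibroblasts and stromal cells with LPS at 6 h, where total counts turned the erythroid list (1 lower, 2 higher) and none of these lists passed camera (adjusted p = 0.212, 0.403, 0.875, 0.078 and 0.143). With LTA at 6 h the numbers were 5 and 0 of 6, 2 and 0 of 3, 0 and 1 of 3, 7 and 0 of 8 and 5 and 0 of 9 in the same order (camera adjusted p = 0.058, 0.427, 0.679, 0.018 and 0.058), and the erythroid list, which passed, had an adjusted p of 0.248 with an estimated correlation. With LTA at 2 h, the inflammatory list was higher in KO in 13 of 31 cases and lower in 8, with a camera adjusted p of 0.0076 and an adjusted p of 0.2 with an estimated correlation.

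Genes called between untreated KO and WT cells were weighed against 2 explanations. For chromosome carried along with the Ticam2 allele, an excess of called genes nearby was not seen. Within 10 Mb, 11 of 97 genes were called (11.3%) against 13.4% elsewhere (1-sided Fisher exact p = 0.77). With so many genes called elsewhere, this share cannot tell whether a few flanking genes changed with the allele, and it does not bear on genetic differences away from Ticam2. A different sex of the animals was argued against, as no library held over 4 counts of Y-linked genes and each held 184 to 4382 of Xist. Neither a difference in genetic background between the WT and KO animals nor a biological explanation was tested. The called genes, Wdfy1 and Nnt among them, can therefore not be assigned to the loss of TRAM from this comparison. Of the genes lower in untreated KO, 49.4% rose at least 2-fold with LPS at 6 h in WT (558 genes, 190 for independent lists), against 4.8% of those higher in KO, which describes the called genes and tests no cause.

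The KO-to-WT differences at 2 h were set against the later WT course of the other ligand, with which they share no libraries. With LPS they had a Pearson r of 0.29 with the WT LTA 6 h response over all tested genes, and 87.5% of the genes called between KO and WT had the same sign (85% with total counts). For LTA against the WT LPS 6 h response the values were 0.23 and 84.9% (79.6%). The ferritin pseudogene Fth-ps2 had 0 counts in the 18 untreated and 2 h libraries and 128 to 172 CPM of the library total in the 12 libraries of 6 h. The pseudogene Fth-ps3 averaged 0.32 CPM untreated and 0.48 at 2 h, was detected in 13 of these 18 libraries, and stood at 87.3 to 121 CPM at 6 h. How counting split reads between these copies and Fth1 was not tested, so their values are uncertain.

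The 6 libraries of a contrast, or for KO against WT the 6 animals over all libraries, can be divided into groups of 3 in 10 ways. These include the real one and are too few for a share under 0.05. Every other split mixes the real groups and so raises the estimated spread, so low counts there could be foreseen. The real split was the 1 with as many called genes in each contrast. For KO against WT the real counts were 2032 untreated, 2472 and 9576 with LPS and 1972 and 8841 with LTA (2 h and 6 h), and the highest other split gave 0 in each. For WT responses they were 6798, 10986, 6499 and 10776 (LPS 2 h, LPS 6 h, LTA 2 h, LTA 6 h) against 2, 0, 3 and 0, and for KO responses 8641, 7908, 8463 and 7898 against 0 in each. For LPS against LTA they were 181 and 4810 in WT and 211 and 402 in KO (2 h and 6 h), against 0, 1, 1 and 1.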
